A study of Mus musculus with 4 samples.

How the data were processed

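DNase-seq libraries of 7438 cells, a mouse mammary cell line with inducible GFP-tagged GR and Cherry-tagged ER, were available for 4 conditions with 1 library each: untreated, Dex, E2 and Dex+E2. Per the labels' protocols, cells were plated 48 h before the experiment, tetracycline was withdrawn 24 h before hormone, and hormones were given at 100 nM for 30 min. The extraction text of the labels mentions sonicated nuclei only and does not describe the nuclease digestion. The groups were taken from the treatment named in each sample's labels.

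The deposited files are lists of hypersensitive regions, 1 list per library, so that regions were called in each library separately. Per the submitters' processing notes the genome build is mm9 and CASAVA 1.8 was used, with no role stated. The aligner, the caller of the regions and its background model are not given in the sources used here. Per the file headers, each region has a maximum and an average tag density, which are signal values that the authors deposited after a scaling per library. In every list 100% of the maximum densities were whole multiples of 1 step within 0.02 tags. The steps were 0.255 untreated, 0.245 after Dex, 0.200 after E2 and 0.227 after Dex+E2, and the step was read as the value of 1 tag. The total to which the libraries were scaled is not stated, and relative depths derived from the steps hold only if it was the same for all. The deposited Z score of each region starts at 4.95 in the untreated, 5.18 in the Dex, 5.26 in the E2 and 5.15 in the Dex+E2 list. The deposited p-value equals the 2-sided normal p of that score, with 0 where it was too small to be written. Scores and p-values belong to single regions against the background of their own library and were not compared between libraries. Regions lay on 20 chromosomes, and none lay on chromosome Y or M. The lists do not state whether positions count from 0 or from 1.

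Regions of 2 lists were taken as shared when they overlapped by at least 1 bp. The 6 pairs of lists were compared by the share of overlapping regions and by the base pair Jaccard index. For each of 5 comparisons, the regions of the treated list without overlap in the reference list and the reverse were counted. The lists were then merged into a union in which overlapping or touching regions were joined, and each union region received 1 of 15 presence patterns. A union region has in each library the highest value of its regions there. A region missing from a list fell short of the authors' threshold in that library, which does not show that its chromatin was closed. With 1 library per condition no p-value for a treatment was computed. Wilson intervals on shares and exact Poisson intervals on the tags at a summit are at the 95% level, treat tags as independent molecules and cover counting error only.

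The design fixed before the data were examined allowed a comparison of densities only if these were scaled to a common depth. Since the scaling total is not stated, ratios are given both as deposited and relative to each library's median over the 20687 regions found in all 4 lists. The calls of 2-fold higher or lower regions, the density of 20 for strong regions, the 2 stretches on chromosomes 8 and 11 and the set of background-type regions, whose deposited density in every hormone library was at least 0.8 of the untreated one, were all defined after the data were examined. For the calls, 1.5-fold and 4-fold limits were looked at as well. A call needed the limit in both comparisons that isolate a hormone, and these share no library. Calls were made only among the 20687 regions in all 4 lists, so a region missing from a list could be called neither higher nor lower. The number of shared calls was set beside the product of both list lengths divided by the number of regions. Random lists of the same size, 10000 per list and matched on the decile of mean density, gave the range for group medians.

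The functions were tested on simulated data. Planted presence patterns were recovered. Tags were simulated for the 20687 shared regions with a spread between libraries of 0.26 on the log2 scale, estimated from a crossed contrast of the same libraries. Of 100 regions raised 2-fold, which lie at the limit, 24% were called for Dex and 23% for E2. Of 100 raised 4-fold, 99% were called for Dex and 100% for E2. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.

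Regions named per comparison are, by the rule fixed before the data were examined, taken from the 10 densest regions of the treated list without overlap in the reference list, the 5 densest of the reverse kind, and the 5 densest of each of 5 presence patterns. Regions named among the 2-fold groups were chosen after their values were seen, by the smaller of their log2 ratios. Alternatives covered the overlap rule, equal list lengths, the denser 50% of a list, joining of regions within 150 bp, chromosome X, the density measure and the scaling. Further alternatives, chosen after the data were examined, were quantile normalization, other fold limits, the omission of libraries and the omission of the background-type regions. A genome sequence and gene annotation for mm9 were not used here, so the planned counts of hormone response elements, the gene annotation of regions and the lists of GR-responsive, ER-responsive, inflammatory, nuclear receptor, AP-1, cell type marker and housekeeping genes were not analysed here.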

Results

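Open chromatin was mapped by DNase-seq, which locates stretches of DNA that the nuclease DNase I reaches easily, in 7438 cells. This mouse mammary line carries a GFP-tagged glucocorticoid receptor (GR) and a Cherry-tagged estrogen receptor (ER), both made when tetracycline is withdrawn, here 24 h before hormone. Cells were left untreated or were treated for 30 min with 100 nM dexamethasone (Dex, a synthetic ligand of GR), with 100 nM estradiol (E2, a ligand of ER) or with both hormones at 100 nM each. The series asks how hypersensitivity changed when both hormones were given together. Each of the 4 conditions had 1 library, so every value describes these libraries, and no effect of a treatment could be tested against the spread between replicates. Positions are given in mm9 as the deposited lists give them, and genes near the regions were not analysed here.

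The untreated list held 65879 hypersensitive regions that covered 45.3 Mb. The Dex list held 51251 regions (31.7 Mb), the E2 list 35496 regions (19.7 Mb) and the Dex+E2 list 50061 regions (29.9 Mb). Read totals were not given in the sources used here. If the authors scaled all tag densities to 1 common total, the Dex, E2 and Dex+E2 libraries were 1.04, 1.28 and 1.12 times as deep as the untreated library, so that the deepest library had the fewest regions. The summit of the median region held 35 tags in the untreated, 32 in the Dex, 37 in the E2 and 36 in the Dex+E2 list. Intervals on densities are exact Poisson 95% intervals for the tags at the summit, those on shares are Wilson 95% intervals, and both cover counting error only.

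Merging the lists gave 103288 regions, of which 20687 were in all 4 lists and 60761 (58.8%) in 1 list only. Most regions of 1 list were weak: 29 of them reached a maximum tag density of 20, against 15203 of the 20687 regions found in all lists. This density of 20, above which a region is called strong here, was chosen after the data were examined. As deposited, it was reached by 15827 untreated, 7460 Dex, 3651 E2 and 8103 Dex+E2 regions. With 1 cut for all libraries, counts of strong regions in 1 list and not in another depend on the scaling of the libraries. Among strong regions missing from the untreated list, 162 were in the Dex and Dex+E2 lists, 71 in the E2 and Dex+E2 lists, 54 in all 3 hormone lists and 2 in the Dex+E2 list alone. In the reverse direction, 75 strong regions were in the untreated and Dex lists only and 16 in the untreated and E2 lists only. A further 66 were missing from the Dex+E2 list only. The Dex list alone held 14781 regions and no strong one, and the untreated list alone held 26861 with 25 strong ones. The base pair overlap (Jaccard index) was highest between Dex and Dex+E2 (48.7%), followed by E2 and Dex+E2 (45.4%), and lowest between untreated and E2 (32.2%). With lists of equal length, untreated and Dex (56.1%) and untreated and Dex+E2 (51.9%) came before E2 and Dex+E2 (49.9%).

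**Figure D1:**
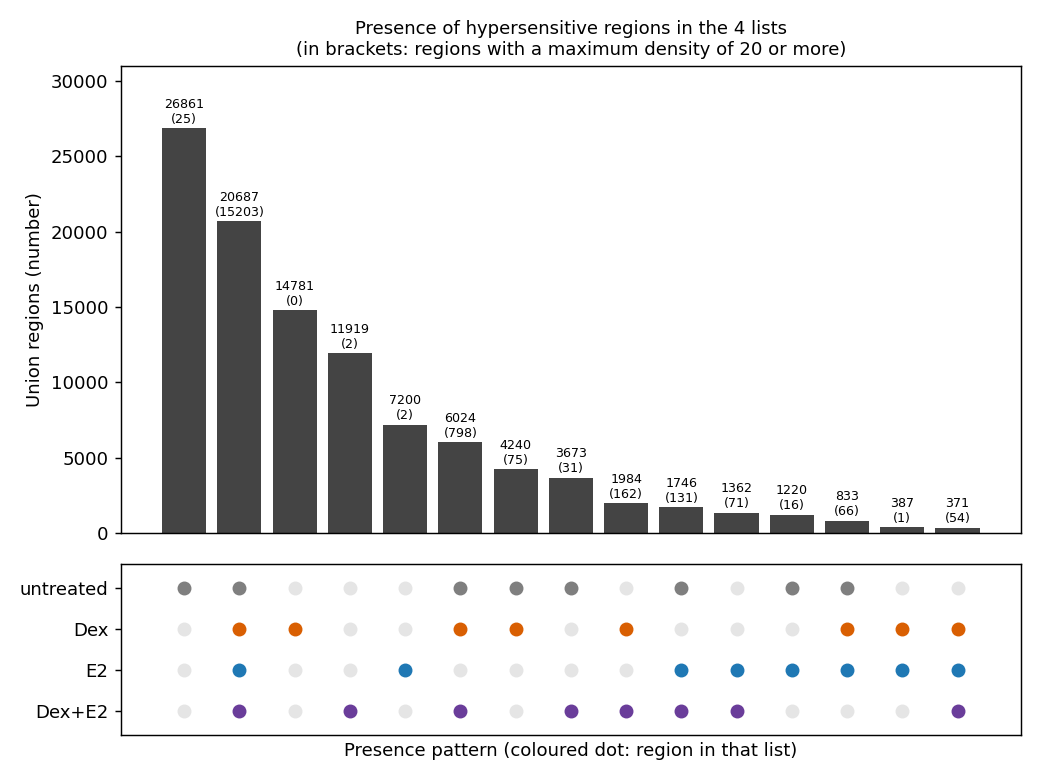
Number of merged regions (vertical axis) in each of the 15 presence patterns, with the lists that hold the region marked by coloured dots; the number in brackets counts regions with a maximum density of 20 or more. The pattern with all 4 lists holds 15203 strong regions, and the untreated list alone holds the most regions (26861) with 25 strong ones.

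The Dex and untreated libraries bear on where activation of GR changed hypersensitivity. The densest Dex region without a counterpart in the untreated list was chr4:59348435-59349477, with a maximum density of 115 (105 to 126) after Dex. The same site reached 80.3 after Dex+E2 and was not listed after E2. Further regions seen with Dex and with Dex+E2 but in neither other list were chr12:80453017-80454115 (79.3 after Dex, 64.7 after Dex+E2), chr17:28649115-28650620 (63.9 and 47.9) and chr8:129331077-129331938 (54.1 and 69.9). The region chr5:144305495-144306399 reached 67.6 after Dex and 81.7 after Dex+E2, and was also listed after E2, at 13.6. On chromosome 18, chr18:9489218-9491064 and chr18:9485239-9487134 reached 65.1 and 63.7 after Dex, and the former was listed at 5.00 after E2. In the other direction, chr1:24560214-24560767 had a density of 40.8 in untreated cells and was in no hormone list. Its Z score was 12.1, against 39.4 and 28.0 at the untreated regions chr10:79131429-79132751 (40.8) and chr1:90158346-90159725 (40.6). Near chr1:24560214-24560767 lies chr1:24619396-24620156, among the densest shared regions (5729 untreated, 2725 after Dex, 1166 after E2 and 1322 after Dex+E2). Whether the latter bears on the former was not tested. The untreated region chr1:90158346-90159725 (40.6) was missing after Dex but listed after E2 (16.6) and Dex+E2 (23.8).

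Of the 51251 Dex regions, 17662 (34.5%, 34.1 to 34.9) overlapped no untreated region, and 33634 of the 65879 untreated regions (51.1%, 50.7 to 51.4) overlapped no Dex region. Strong regions made up 145 of the former and 156 of the latter, out of 7460 strong Dex and 15827 strong untreated regions. With each list reduced to its 35496 densest regions, the counts were 8276 and 9392. Merged regions that were in the Dex list and not in the untreated list and had a density of at least 20 in the Dex library itself numbered 144, of which 144 (100%, 97.4 to 100) were in the Dex+E2 list and 16 (11.1%, 6.96 to 17.3) in the E2 list, which is the shorter of these. When all 17523 such regions were counted, weak ones included, 13.4% were in the Dex+E2 list and 4.33% in the E2 list. Among all 7460 strong regions of the Dex list, in the untreated list or not, 1 overlapped no Dex+E2 region. The 100% is therefore not particular to regions missing from the untreated list.

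After E2, the region chr15:101337379-101338203 had a density of 26.8 (22.5 to 31.7) with no counterpart in the untreated list, and the same site reached 44.5 after Dex+E2. The region chr4:134658085-134659088 was also at 26.8 after E2, with 12 after Dex and 51.7 after Dex+E2. At chr15:25572845-25573653 the density was 31.2 after E2, although other regions of the same merged site were listed in untreated cells, at up to 31.6. The remaining 7 of the 10 densest regions listed after E2 and not in untreated cells lay in 2 narrow stretches, chr8:19523820-20033218 and chr11:3022057-3166752. In these stretches densities hardly differed between libraries: the 64 shared regions of the chromosome 8 stretch had medians of 24.5 untreated, 25.3 after Dex, 27.3 after E2 and 26.3 after Dex+E2. Regions of untreated cells missing after E2 included chr15:78636893-78638116 (43.9, with 13.5 after Dex) and chr15:98702223-98703052 (42.6, with 23.8 after Dex and 15.4 after Dex+E2).

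In total 9453 of 35496 E2 regions (26.6%, 26.2 to 27.1) overlapped no untreated region, and 41178 of 65879 untreated regions (62.5%, 62.1 to 62.9) overlapped no E2 region. The strong ones numbered 15 and 751, out of 3651 strong E2 and 15827 strong untreated regions. Lists of equal length gave 11899 and 13267. Merged regions in the E2 list and not in the untreated list with a density of at least 20 in the E2 library itself numbered 13, of which 8 lay in the 2 stretches, which were chosen after the data were examined. The other 5 were all in the Dex+E2 list, and 2 of them were in the Dex list. Of all 9320 such regions, weak ones included, 18.6% were in the Dex+E2 list and 8.13% in the Dex list. Among all 3651 strong regions of the E2 list, in the untreated list or not, 5 overlapped no Dex+E2 region.

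Co-treatment against no hormone bears on the joint activation of both receptors. The densest regions listed after Dex+E2 and not in untreated cells were chr5:144305494-144306418 at 81.7 (73.5 to 90.6), chr4:59348453-59349795 at 80.3 and chr8:129330987-129331941 at 69.9. A region with values after each hormone alone was chr4:47510430-47511420, which reached 11.02 after Dex, 22.0 after E2 and 58.5 after Dex+E2. At chr15:25656269-25657185 the values were 47.3 after Dex, 9.40 after E2 and 59.0 after Dex+E2. Regions seen after co-treatment alone were weaker, led by chr15:100122786-100123524 (34.9) and chr16:11211433-11212082 (21.8). Untreated regions missing after Dex+E2 included chr1:81734475-81735592 (46.4 untreated, 14.0 after Dex and 7.80 after E2) and chr3:58145761-58146592 (40.6, 7.35 and 9.60). The Dex+E2 list had 15808 of 50061 regions (31.6%, 31.2 to 32.0) without an untreated counterpart, 223 of them strong, and 33419 of 65879 untreated regions (50.7%, 50.3 to 51.1) had no Dex+E2 counterpart, 183 of them strong. With equal list lengths these were 8228 and 9681. In all, 8103 Dex+E2 and 15827 untreated regions were strong.

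**Figure D2:**
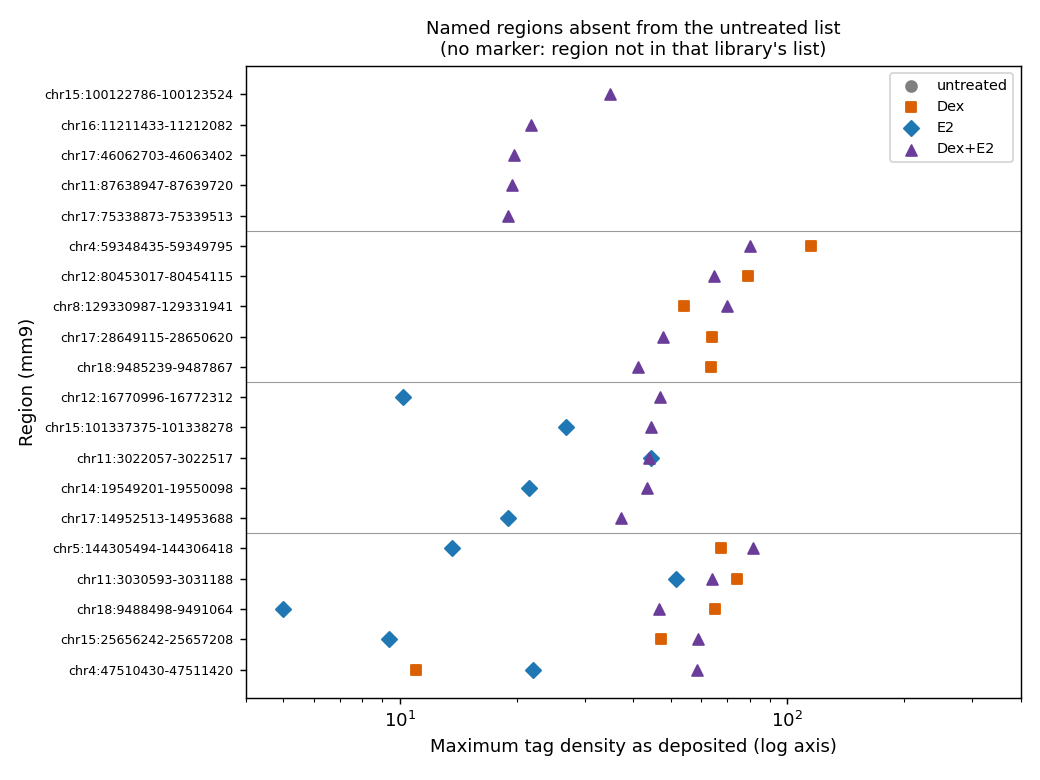
Maximum tag density as deposited (log axis) at the 5 densest merged regions of each of 4 presence patterns without the untreated list, from top to bottom Dex+E2 alone, Dex and Dex+E2, E2 and Dex+E2, and all 3 hormone lists; a missing marker means that the region was not in that library's list. Regions of Dex+E2 alone stay at or under 34.9, whereas chr4:59348435-59349795 reaches 115 after Dex.

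The Dex+E2 and Dex libraries differ in whether E2 was given, but with 1 library each their differences cannot be assigned to E2. The densest region listed after Dex+E2 and not after Dex was chr8:13506459-13507423 at 62.6 (55.4 to 70.5), which stood at 34.8 after E2 and 13.0 in untreated cells. On chromosome 12, chr12:16770996-16772312 reached 47.0 after Dex+E2 and 10.2 after E2, and chr12:17149486-17150376 reached 41.7, with 19.4 after E2 and 8.67 untreated. Both chr15:101337375-101338278 (44.5 after Dex+E2, 26.8 after E2) and chr14:19549201-19550098 (43.6 and 21.6) were in no list without E2. Of the Dex+E2 regions, 19103 (38.2%, 37.7 to 38.6) overlapped no Dex region, 130 of them strong. In the reverse direction 21167 of 51251 Dex regions (41.3%, 40.9 to 41.7) overlapped no Dex+E2 region, and 1 of them was strong, chr11:3038299-3038686 (46.8), which lies in the chromosome 11 stretch at a merged site found in all 4 lists. Equal list lengths gave 8934 and 9680.

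Between the Dex+E2 and E2 libraries the treatment differs in Dex, and here too differences between single libraries cannot be assigned to the hormone. The region chr4:64255821-64256908 led with 118 (108 to 129) after Dex+E2, 123 after Dex and 16.3 untreated, and was not listed after E2. Both libraries with Dex also exceeded the untreated one at chr4:55788554-55789622 (64.9 after Dex+E2, 52.7 after Dex, 14.3 untreated), chr2:152611018-152612301 (56.3, 68.6 and 16.1) and chr17:28652431-28653473 (54.0, 63.9 and 10.7), with no listing after E2. Of the Dex+E2 regions, 24866 (49.7%, 49.2 to 50.1) overlapped no E2 region, 234 of them strong. Conversely, 9853 of 35496 E2 regions (27.8%, 27.3 to 28.2) overlapped no Dex+E2 region, and the 5 strong ones all lay in the 2 stretches. With equal list lengths the counts were 12376 and 11897. Where a region mostly overlaps a single region of the other list, lists of equal length must give similar counts. These counts therefore cannot show how far list length accounts for the imbalance.

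Across the 20687 regions of all 4 lists, densities as deposited were lower in every hormone library than in the untreated one. The median density was 30.1 untreated, 14.7 after Dex, 10.2 after E2 and 15.4 after Dex+E2. The median log2 ratio to untreated was −1.04 for Dex, −1.56 for E2 and −0.95 for Dex+E2, and 90.1% of regions were lower in all 3 hormone libraries. Dex+E2 differed from Dex by a median log2 of 0.05 and from E2 by 0.56. With 1 untreated library, this shift could not be separated from a difference between libraries, so changes at single regions are given relative to each library's median over these regions. On the deposited scale, 114 regions were at least 2-fold higher and 11190 at least 2-fold lower after Dex than untreated, against 1384 and 123 relative to the medians. For E2 the deposited scale gave 33 and 17348, against 1631 and 92. Of these higher regions, 663 of 1384 for Dex and 876 of 1631 for E2 were background-type regions, whose deposited density in every hormone library was at least 0.8 of the untreated one. For E2, division by the medians alone puts every such region above 2-fold.

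**Figure D3:**
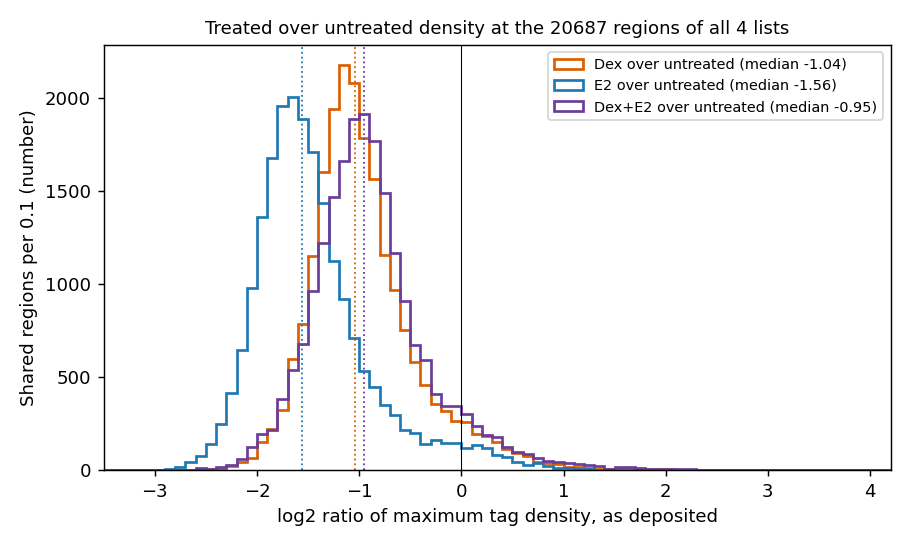
Histogram of the log2 ratio of maximum tag density as deposited (horizontal axis, bins of 0.1) between each hormone library and the untreated library over the 20687 shared regions (vertical axis, number of regions); dotted lines mark the medians. All 3 distributions lie mostly below 0, with medians of −1.04, −1.56 and −0.95.

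Dex-higher regions were those at least 2-fold higher in both comparisons that isolate Dex, Dex over untreated and Dex+E2 over E2, which have no library in common; this rule was set after the data were examined. The leading region, chr18:9491174-9494839, had densities of 6.12 untreated, 84.5 after Dex, 5.40 after E2 and 51.0 after Dex+E2, which is 28.3-fold and 6.25-fold relative to the library medians. At chr7:117926276-117927250 the densities were 8.42, 83.5, 9.20 and 85.3 in the same order (20.3-fold and 6.13-fold). The site chr12:76404928-76406074 (10.5, 49.0, 6.60 and 58.3) was 9.59-fold and 5.84-fold higher, and chr19:44299872-44301017 (28.1, 102, 10.4 and 89.8) was 7.46-fold and 5.71-fold higher. Regions 2-fold lower with Dex were few, led by chr15:33573136-33574621, with 77.5 untreated, 12.2 after Dex, 31.0 after E2 and 17.5 after Dex+E2 (log2 −1.63 and −1.42).

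There were 285 Dex-higher and 9 Dex-lower regions, where independent lists of the same sizes would share 24.6 and 1.28. Of the 285, 28 were background-type, and 243 regions were called when that type was left out and the medians were taken over the others. Of the 20487 regions left unchanged in the simulated libraries, 7 and 6 were called. In 100 further simulations with no planted change, at most 32 background-type regions arose, against 876 in the data. Since the simulation lacks most such regions, 7 and 6 do not give the rate of false calls in the real libraries. As deposited, without the medians, 93 regions were higher and 2 lower. Leaving out the E2 library, so that both Dex libraries were set against the same untreated one, gave 886 higher and 46 lower regions. Leaving out the untreated library set both against the same E2 library and gave 282 and 43. In either case both comparisons share a reference library, whose noise enters both, so these counts are no independent check. Across the shared regions, which are not independent replicates, the log2 differences of both Dex comparisons had a Pearson r of 0.24 and a Spearman rho of 0.14.

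E2-higher regions were defined in the same way from E2 over untreated and Dex+E2 over Dex. At chr12:25408067-25409727 densities were 18.9 untreated, 12.7 after Dex, 45.2 after E2 and 86.4 after Dex+E2, or 7.07-fold and 6.46-fold relative to the medians. Densities at chr12:16797065-16797819 were 9.44, 10.0, 36.2 and 66.2 (11.3-fold and 6.28-fold), and those at chr11:53128015-53128849 were 6.89, 8.33, 20.6 and 49.0 (8.83-fold and 5.61-fold). The region chr15:77970307-77971230 had 22.2, 11.02, 41.0 and 59.7 (5.45-fold and 5.16-fold). Among the 6 E2-lower regions, chr6:29228370-29229399 led with 47.2 untreated, 22.5 after Dex, 6.20 after E2 and 8.85 after Dex+E2 (log2 −1.37 and −1.42).

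The E2-higher regions numbered 206 and the E2-lower regions 6, against 30.0 and 0.818 for independent lists. Among 20487 simulated unchanged regions 6 and 6 were called, with the same limit as for Dex. Of the 206, 54 were background-type, and 168 regions were called when that type was left out in the same way. The balance between higher and lower depended on the scaling: on the deposited scale 19 regions were higher and 109 lower. Without the Dex library the counts were 958 and 21, and without the untreated library 234 and 49. In these settings too, both comparisons share a reference library, untreated in the former and Dex in the latter. Pearson r between both E2 comparisons was 0.30 and Spearman rho 0.28 across regions.

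**Figure D4:**
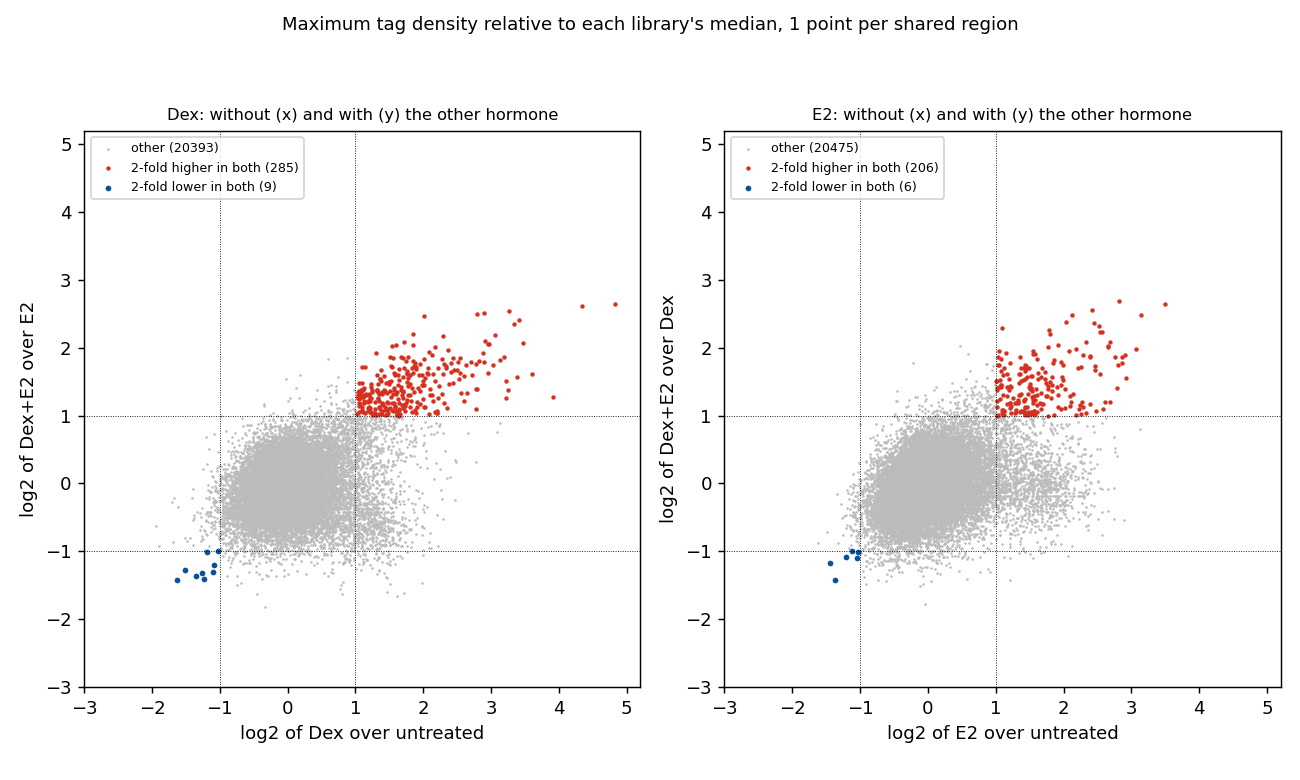
Each point is 1 of 20687 shared regions, placed by the log2 ratio of maximum tag density relative to library medians without the other hormone (horizontal) and with it (vertical), for Dex (left) and E2 (right). Red points are the 285 Dex-higher and 206 E2-higher regions and blue points the 9 and 6 lower ones; as deposited, without the medians, the median E2 over untreated of the 201 E2-higher regions that are not Dex-higher is −0.02.

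The medians of each group for its own hormone are set by the choice of the regions. In the 280 Dex-higher regions that were not E2-higher, the median log2 was 1.65 for Dex over untreated and 1.36 for Dex+E2 over E2 (0.61 and 1.96 as deposited). E2 over untreated had a median of 0.12 in these regions (−1.44 as deposited, −0.01 after quantile normalization), above the 95% range of 10000 random lists matched on density (−0.15 to −0.04). Dex+E2 over Dex had a median of −0.16 there (−0.09 as deposited, −0.18 after quantile normalization), below its random range (−0.06 to 0.06). In the 201 regions that were E2-higher and not Dex-higher, the median was 1.54 for E2 over untreated (−0.02 as deposited) and 1.40 for Dex+E2 over Dex (1.47 as deposited). Dex over untreated was 0.24 in them (−0.80 as deposited, 0.03 after quantile normalization), and Dex+E2 over E2 was 0.10 (0.70 as deposited, 0.01 after quantile normalization), both above their random ranges (−0.07 to 0.06 and −0.09 to 0.05). In each of these 4 ratios for the other hormone, both libraries entered the choice of the regions, which acts on the ratio in both directions and was not part of the random lists.

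Regions in both groups numbered 5, where 2.84 would be shared by independent lists; both groups rest on the same 4 libraries. They were chr11:106822528-106823481, chr5:67696535-67697361, chr12:74086879-74087647, chr15:59630626-59631628 and chr18:63709950-63710718. The first had densities of 7.40 untreated, 19.1 after Dex, 10.2 after E2 and 52.6 after Dex+E2, or 5.29-fold, 4.07-fold and 13.9-fold over untreated relative to the medians. At chr15:59630626-59631628 the densities were 17.6, 32.3, 22.6 and 74.4. Over all shared regions, the Dex difference was at least 2-fold larger with E2 than without it at 220 regions and at least 2-fold smaller at 1657, relative to the medians. Equal deposited densities in all libraries already give a log2 of 1.03 for Dex over untreated and −0.60 for Dex+E2 over E2 on this scale, and 781 of the 1657 regions were background-type. The balance depended on the scaling: the counts were 17396 and 38 as deposited, 489 and 775 after quantile normalization and 542 and 1714 with the average density. Differences of 4-fold numbered 0 larger and 265 smaller relative to the medians, with 237 of the latter background-type, and 4129 and 0 as deposited.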

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

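The test for counting noise was chosen only after the result was seen. Dex differences went in opposite directions without and with E2 at 53 of the shared regions, which were at least 2-fold higher in Dex than in untreated cells and at least 2-fold lower in Dex+E2 than in E2, relative to the library medians. The difference was not tested, since there were no replicates. By the sum of the sizes of both log2 ratios, the first was chr13:68456858-68458707, with densities of 2.30 untreated, 4.41 after Dex, 5.80 after E2 and 3.18 after Dex+E2. It was followed by chr13:65616251-65616772 (2.30, 3.67, 4.60 and 2.27). The untreated density of both lies close to the lowest in the untreated list, 2.04, so their ratios rest on few tags. As a set the 53 regions were weak, with median densities of 5.10 untreated, 6.37 after Dex, 7.0 after E2 and 4.54 after Dex+E2.

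Several accounts of these 53 regions were weighed. To stand for counting noise that is independent between both comparisons, the higher and the lower calls were reassigned at random. Within 10, 50 or 200 groups of equal density, the upper ends of the 95% ranges were 35, 43 and 46, below 53. That limit rises as the groups get finer, and finer groups were not tried, so counting noise is not excluded. Signal of a background type stays open. Of the 53 regions, 45 (84.9%) were at 0.8 or more of the untreated density in every hormone library, against 876 (4.23%) of all shared regions, although the same ratios enter both choices. Such signal was expected to lack a sharp summit, and the median ratio of maximum to average density was 4.30 in the 53, above the range of 3.83 to 4.23 in random lists of equal density. This decides nothing, because the 876 regions themselves, checked afterwards, had a ratio of 4.33, above their random range of 4.04 to 4.14, so that the expectation did not hold for that set. A trend with density that a single median per library leaves in may account for most of the count: after quantile normalization 16 such regions were found, 8 of them among the 53. For those that stayed, a Dex response that turns in the presence of E2 remains open and untested.

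For E2, 10 shared regions were at least 2-fold higher than untreated after E2 alone and at least 2-fold lower in Dex+E2 than in Dex, and this difference was not tested either.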

How the results depend on the processing

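Of 218 values under alternatives, 132 stayed within the limits set for them and 86 moved; the cause was not tested unless the alternative itself fixes it. Alternatives on the 2-fold calls other than the density measure and the restriction to dense regions were chosen after the data were examined, as were all alternatives on the Dex difference with against without E2. No paired analysis was possible because each condition has 1 library and no result comes from a test. Not run were the alternatives for response elements, gene annotation and gene lists. Read totals were not given in the sources used here, so how far depth limits the weak regions was not tested.

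The overlap rules, joining within 150 bp and leaving out chromosome X moved none of the values they were applied to. Chromosome X held 2148 of the 65879 untreated and 1006 of the 35496 E2 regions, so leaving it out could not move these list lengths beyond 1.5-fold. Regions at or above the median density of the shortest list numbered 39308 untreated, 26801 for Dex, 17971 for E2 (12.9 Mb) and 28463 for Dex+E2; a stricter limit lowers such counts by construction. Equal list lengths gave 8276 Dex and 9392 untreated regions without counterpart in that comparison, 13267 untreated regions against E2, 8228 and 9681 for Dex+E2 against untreated, 8934 and 9680 for Dex+E2 against Dex, and 12376 Dex+E2 regions against E2. They left 4368 regions in Dex+E2 alone, 5432 in untreated alone and 23450 in any hormone list without untreated. Taking the denser 50% of the list in question against the whole other list gave 2188 and 6191 for Dex against untreated, 948 and 11151 for E2 against untreated, 2573 and 6079 for Dex+E2 against untreated, 2891 and 2551 for Dex+E2 against Dex, and 5034 and 636 for Dex+E2 against E2. The patterns were then 869 for Dex+E2 alone, 706 for Dex and Dex+E2, 419 for E2 and Dex+E2, 88 for all 3 hormone lists, 3193 for untreated alone and 4217 for any hormone without untreated.

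Median log2 ratios at shared regions, in the order Dex, E2 and Dex+E2 over untreated, Dex+E2 over Dex and Dex+E2 over E2, were −1.03, −1.36, −0.85, 0.15 and 0.47 with the average density, and −1.13, −1.70, −1.01, 0.0844 and 0.66 in regions above the median of all 4 lists. Division by the library medians sets them near 0 by construction (−0.00848, 0.00119, 0.00969, −0.0155 and −0.0332), and these 5 are among the 86 that moved.

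For Dex, higher and lower 2-fold calls were 59 and 0 in regions above the median of all 4 lists, 93 and 2 as deposited, 752 and 229 at 1.5-fold and 15 and 0 at 4-fold. They were 886 and 46 without the E2 library, and 43 regions were lower without the untreated library. For E2 they were 30 and 0 in the dense regions, 19 and 109 as deposited, 681 and 289 at 1.5-fold, 14 and 0 at 4-fold, and 958 and 21 without the Dex library. E2-lower regions numbered 13 with the average density, 13 after quantile normalization, 3 without the background-type regions (at least 0.8 of the untreated density in every hormone library) and 49 without the untreated library. Of the 285 Dex-higher regions 258 were kept after quantile normalization, 223 with the average density and 77 as deposited; of the 206 E2-higher regions these were 183, 131 and 18.

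Relative to the medians, the Dex difference was at least 2-fold larger with E2 at 220 regions and smaller at 1657. These counts were 17396 and 38 as deposited, 489 and 775 after quantile normalization, and 542 and 1714 with the average density. At 4-fold they were 0 and 265 relative to the medians, 4129 and 0 as deposited, 10 and 63 after quantile normalization, and 14 and 231 with the average density. Without the background-type regions, 876 regions were 2-fold and 28 4-fold smaller with the medians kept, and 978 and 38 with the medians taken anew; 220 and 168 were then 2-fold larger.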

Other observations

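The 6 densest shared regions stood far above the rest. The first, chr13:85266243-85267370, had densities of 15878 untreated, 7501 after Dex, 3270 after E2 and 3413 after Dex+E2, and the lowest of the 6 in the untreated library had 5225, against 1260 for the densest of the other regions. Dex+E2 over Dex was −1.14 on the log2 scale at the first, although the median over all shared regions was 0.05. All 20 chromosomes were looked at for each hormone with no test, and the largest excess for each is given here. On chromosome 2 lay 34 of the 285 Dex-higher regions, where its share of shared regions gives 20.7, and on chromosome 9 lay 19 of the 206 E2-higher regions, where its share gives 10.2. Chromosome X held 6 Dex-higher regions (7.07 by its share) and 0 E2-higher regions (5.11 by its share).

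The tests on the shift between libraries were chosen only after the result was seen, as were the stretch they use and the groups of 2-fold higher regions. The untreated library had the higher density at 90.1% of shared regions in comparison with all 3 hormone libraries. If 1 factor per library were the cause, the shift would be alike everywhere. The 64 shared regions of the chromosome 8 stretch argue against this: their median log2 of E2 over untreated was 0.16 with a lower quartile of −0.09, whereas the upper quartile of all shared regions was −1.22. The stretch holds several of the densest regions listed after E2 and not in untreated cells, so its choice may favour a high E2 ratio. Its medians over untreated were also 0.09 for Dex and 0.07 for Dex+E2, where the upper quartiles of all shared regions were −0.72 and −0.63. These ratios rest on the same untreated library, so the choice of the stretch may favour them too, and they are not independent of the E2 ratio. A candidate explanation is that libraries differed in how much of their signal came from hypersensitive sites. This and an effect of hormone treatment of any kind cannot be told apart, because there was no further untreated library.

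Dex-higher regions lay near one another more often than random lists of equal density. Of the 285, 10.9% had another within 50 kb, where random lists gave up to 7.02% (upper end of the 95% range). A single site split into regions nearer than 5 kb to one another does not account for this alone. Of the 285, 8.77% still had such a neighbour at 5 to 50 kb, above the random range of 0.702 to 6.67%. Single regions of the Dex list were up to 14720 bp wide, so wider sites split into parts further apart are not excluded. As a hypothesis, responses to Dex may come in groups of sites. For the E2-higher regions the share within 50 kb was 5.83%, equal to the upper end of the random range, so chance placement was not excluded for them.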
